A study of Rattus norvegicus with 16 samples.

How the data were processed

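RNA from primary hepatocytes of male Sprague Dawley rats was compared on 16 Agilent arrays, each of which held RNA from 1 treated and 1 untreated culture. Per the labels, cells in Williams Medium E were left untreated or given 100 µM SQ1 or 30 µM pravastatin 48 hours after plating, for 48 hours. RNA was amplified in 1 round to aminoallyl RNA and coupled to an Alexa dye, A555 or A647. For each drug, 8 arrays were hybridised, 4 in each dye orientation, and GEO's design text calls them biological replicates.

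The authors scanned the arrays and measured spots with Agilent Feature Extraction, per their processing notes, in version 10.7.1.1 per the file headers. The deposited scanner files give the median brightness and the median local background of each spot in each colour as intensity in arbitrary units. Per the file headers, processed signals are also intensity, after background subtraction, spatial detrending and dye normalisation, and the ratio column is the log10 of the red over the green processed signal. The values of the deposited table are log2 of treated over untreated, with 1 value per probe. Its columns held, in every case, the values of the same-numbered array of the other drug, with a correlation across probes of 0.938 to 1.00 and a slope of 0.998 to 1.01, against 0.422 to 0.562 with the array of the column's own label. Sample groups and dye orientation were taken from the sample labels and the scanner files under them, and the value table was used only as an alternative.

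Each array held 44254 spots, of which 1377 were controls and 42877 carried 30367 distinct probes. Probes were named by the RefSeq accession that the files give, through the RefSeq annotation of assembly GRCr8, which named 17998 probes and left 12369 under their own identifiers. The files state the older build rn4, and no coordinates are given here for that reason. The median signal of an array was 588 to 663 in the A555 channel, over a background of 306 to 315, and 790 to 1076 in the A647 channel, over 339 to 348. The spots well above background made up 71.3% to 86.2% in the first channel and 72.4% to 85.2% in the second. No spot was saturated, and at most 27 spots of an array were left out as non-uniform. The number of arrays limits the precision of each value.

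Log ratios were computed in R 4.3.3 with limma 3.58.1, statmod 1.5.0, jsonlite 2.0.0 and version 1.17.8 of data.table. Median signals were used where mean signals had been planned, since only medians are among the columns of the scanner files. Background was removed by the normexp method with an offset of 50, and each array was normalised by loess with control spots at weight 0. Spots of a probe were averaged, and probes well above background in at least 6 of the 32 channel measurements were kept. The probe with the highest mean signal stood for a gene with several probes, which left 20395 genes, 11937 of them with a symbol. Probes without a symbol count as genes of their own.

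A linear model with a term for each drug and a dye term for each gene was fitted with limma and its moderated variances over all 16 arrays. The comparisons were SQ1 against untreated, pravastatin against untreated, and SQ1 minus pravastatin. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, in tests that were two-sided. Scanner file names hold the same control number on same-numbered arrays of both drugs. The residuals of same-numbered arrays correlated at 0.139 to 0.629, each above 0.1. For replicates 2, 7 and 8 an array of another number correlated more, at 0.364, 0.391 and 0.328. The arrays were also fitted with the replicate number as a block, random (correlation 0.394) or fixed. File names and scans split the arrays into 2 culture series, each with 4 arrays of either drug, and 4 slides, each of which held 1 drug and 1 culture series. No label names a culture series: the split was read from the control numbers in the file names, and it coincides with the 2 scan days. A difference between the series can therefore not be told apart from one of scan day or slide. No slide held both drugs, so a difference between the drugs cannot be told apart from one between slides either.

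The 23 gene lists included cholesterol synthesis, sterol-regulated uptake and sensing, LXR targets, fatty acid and triglyceride synthesis, CAR and PXR targets, PPARalpha targets, AHR targets, NRF2 targets, actin and SRF targets, YAP targets, hepatocyte function, bile acid synthesis and transport, glucose metabolism, endoplasmic reticulum and integrated stress, heat shock, cell cycle, p53 targets, acute phase and inflammation, and markers of macrophages, of stellate cells and fibroblasts, of endothelial cells and of cholangiocytes. They were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The rotation test fry served as an alternative that asks whether a list's genes move one way, without setting them against other genes. With the replicate block, camera was run on z values of the blocked model, a scale taken up after a first run on its moderated statistics had been seen. The model, comparisons, lists, gene rule and most alternatives were fixed before the data were examined.

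By that rule, the named genes were the 10 that rose most and the 10 that fell most in each comparison with 1 sign on all 8 arrays (for the difference, in at least 7 of 8 pairs), up to 4 members of each list with the largest called change or, where no member was called, the brightest one, and a fixed set of genes, most of them of sterol and drug metabolism. The text prints a subset of them that was chosen after their values had been seen. Some named genes and 1 gene list are not reported here. Cyp2b1 and Srebf1 belong to the fixed set but had no probe named by accession.

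The shared response was measured as the correlation and covariance of the log2 fold changes of both drugs across genes. It was set against 100 simulations of unchanged genes with shared controls, against the overlap of independent lists, and against fits in which the drugs shared no controls. The model was tested on simulated data with 200 changed genes among 20366. It called 44 of 50 genes changed by 0.25 on the log2 scale, 49 of 50 at 0.5, 50 of 50 at 1 and 50 of 50 at 2, none with the wrong sign, and 4.93% of its 203 calls were unchanged genes. The simulated noise was independent between arrays and drawn from the model that was fitted. These rates therefore do not cover correlated arrays or differences between culture series.

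Alternatives were the Agilent processed signals, no background subtraction, an offset of 16, median centring, quantile normalisation of mean signals, scaling between arrays, no filter or one at 16 of 32 channels, the mean of a gene's probes, each probe on its own, no dye term, a drug's own arrays alone, replicate and slide blocks, culture series as a term and singly, array weights, the value table as labelled and as matched to the scanner arrays, a 1.5-fold minimum, an adjusted p under 0.01, and leaving out each array. Scaling between arrays and the matched value table were added after the data had been seen. Plots were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.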

Results

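Transcript levels were measured in cultured rat hepatocytes on 16 arrays, 8 that compared cells treated with SQ1 to untreated cells and 8 that did so for pravastatin. SQ1, a code name in the labels, is known from hepatocyte studies as squalestatin 1, an inhibitor of squalene synthase, which makes the first committed intermediate of sterol synthesis. Pravastatin, a statin, blocks the same pathway further upstream. The doses differed (100 µM SQ1 and 30 µM pravastatin), as printed in the labels. The SQ1 dose looks high for squalestatin 1, and no file allowed a check of it. Values are log2 fold changes of treated over untreated cells with the SE of the model, n = 8 arrays per drug. Log ratios correlated across genes at 0.753 to 0.957 between SQ1 arrays and at 0.569 to 0.911 between pravastatin arrays, and genes are not independent replicates. Each of the 77 genes given with a value in the comparisons below had at least 1 probe above background in each channel of every array. For a gene with several probes, that need not be the probe whose value is given. Drug names follow the scanner files, from which the deposited value table differs by an exchange of the drugs.

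The first comparison asked which transcripts change when squalene synthase is inhibited. On the arrays labelled SQ1, all 20 measured genes of the cholesterol synthesis list rose, by a median of 2.75. Idi1, the isomerase that makes dimethylallyl diphosphate, rose by 4.30 ± 0.08 or 19.8-fold, and Acat2, the thiolase at the start of the pathway, by 3.94 ± 0.07. Sqle, squalene epoxidase, rose by 2.81 ± 0.06, and Fdft1, squalene synthase itself, by 1.63 ± 0.05. When arrays were scaled to 1 spread, Fdft1 was at 1.27 and lost its call (adjusted p = 0.090). The largest rise of a gene with a symbol was that of Scd2, a fatty acid desaturase, at 4.47 ± 0.13 or 22.1-fold. The cholesterol list passed its test (adjusted p = 8.1e-19), with an adjusted p = 0.057 with an estimated correlation, and its median was 2.88 in the first culture series and 2.52 in the second.

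Other sterol genes also rose with SQ1. In the list of sterol-regulated uptake and sensing, 8 of 9 genes rose and 1 fell (median 0.77, 1.43 with the Agilent processed signals; adjusted p = 0.00042; adjusted p = 0.11 with an estimated correlation). Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, rose by 2.91 ± 0.04. Of 9 LXR targets, 3 rose and 5 fell, and the list did not pass (median −0.20, −0.09 with median centring; adjusted p = 0.71). Among them Abcg5, a sterol exporter, rose by 1.76 ± 0.13 and Abcg1, a cholesterol exporter, fell by 0.76 ± 0.10, while Abca1 stood at 0.10 ± 0.05 (adjusted p = 0.085). Abca1 passed without SQ1 replicate 7 (adjusted p = 0.034), with the Agilent processed signals (adjusted p = 0.033), with median centring (adjusted p = 0.046) and with the culture series as a term (adjusted p = 0.047). It also passed within the first culture series, at 0.22 (adjusted p = 0.025). Fatty acid and triglyceride synthesis had 8 of 14 genes up and 5 down (median 0.41, adjusted p = 0.052), and passed with the random replicate block (adjusted p = 0.047), with no filter (adjusted p = 0.027) and within the first culture series (adjusted p = 0.021). Its risers included Fads1, a fatty acid desaturase, at 2.59 ± 0.03 and Elovl6, a fatty acid elongase, at 2.53 ± 0.10.

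Genes of drug and fatty acid catabolism rose strongly with SQ1. Of 19 CAR and PXR targets, 13 rose and 5 fell (median 0.53, adjusted p = 0.020; adjusted p = 0.25 with an estimated correlation). Cyp2b2, a drug-metabolising cytochrome P450 and classical CAR target, rose by 3.19 ± 0.09 or 9.16-fold, Ugt2b1, a glucuronosyltransferase, by 2.64 ± 0.11, Cyp3a23-3a1 by 1.94 ± 0.14 and Cyp3a2 by 1.26 ± 0.07, whereas Cyp2c7 fell by 2.29 ± 0.09. Of 30 PPARalpha targets, 27 rose and 3 fell (median 0.61, adjusted p = 6.4e-11; adjusted p = 0.057 with an estimated correlation). Acot1, an acyl-CoA thioesterase, rose by 2.93 ± 0.04, Cyp4a2, a fatty acid hydroxylase, by 2.79 ± 0.10, Pdk4, a kinase that shuts off pyruvate dehydrogenase, by 1.91 ± 0.09, and Cyp4a1 by 0.76 ± 0.06. Of 14 NRF2 targets, 9 rose and 3 fell (median 0.24, adjusted p = 0.037; adjusted p = 0.20 with an estimated correlation), with Hmox1, heme oxygenase, at 1.47 ± 0.06. Probes for the Cyp2b, Cyp3a, Cyp4a, Gst, Ugt2b and Scd families can bind close paralogs, so values of single members are uncertain.

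Genes of differentiated hepatocytes fell with SQ1. All 20 genes of the hepatocyte function list fell (median −0.70, adjusted p = 2.1e-10; adjusted p = 0.076 with an estimated correlation), among them Cyp2c11, a male-specific cytochrome P450, by 2.14 ± 0.05 and Cps1, the entry enzyme of the urea cycle, by 1.59 ± 0.07. All 15 genes of bile acid synthesis and transport fell (median −1.35, adjusted p = 1.7e-09; adjusted p = 0.088 with an estimated correlation). Slc10a1, the bile acid uptake carrier, fell by 2.53 ± 0.12, Slc27a5, the bile acid ligase, by 2.14 ± 0.06, Cyp8b1, which makes cholic acid, by 2.06 ± 0.08, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 1.74 ± 0.13. Among 13 genes of glucose metabolism 7 fell and 3 rose, and the list did not pass (median −0.23, adjusted p = 0.058). It passed within the first culture series, at a median of −0.15 (adjusted p = 0.026), with no filter (adjusted p = 0.029) and with the filter at 16 of 32 channels (adjusted p = 0.047). G6pc1, glucose-6-phosphatase, fell by 3.02 ± 0.06 and Pklr, liver pyruvate kinase, by 2.64 ± 0.11. On these arrays macrophage, stellate and endothelial markers fell as well.

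All 15 macrophage markers fell with SQ1 (median −0.53, adjusted p = 2.1e-06; adjusted p = 0.20 with an estimated correlation), for example Aif1 by 0.77 ± 0.07 and Cd14, a receptor for bacterial lipopolysaccharide, by 0.72 ± 0.07. Of 11 stellate cell and fibroblast markers, 10 fell (median −0.59, adjusted p = 0.00022; adjusted p = 0.057 with an estimated correlation), among them Lrat, which stores retinol as esters, by 0.81 ± 0.06 and Col3a1, a fibrillar collagen, by 0.77 ± 0.05. Of 7 endothelial markers, 6 fell (median −0.26, −0.47 with the Agilent processed signals; adjusted p = 0.0055; adjusted p = 0.057 with an estimated correlation), including Lyve1 by 0.80 ± 0.08. Of 7 cholangiocyte markers, 2 rose and 3 fell (adjusted p = 0.80), with a median of −0.01 (−0.18 with the Agilent processed signals) and a mean of 0.05, and Epcam, an epithelial adhesion molecule, rose by 0.57 ± 0.03.

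Growth and stress genes split by list. The cell cycle list had 16 of 21 genes down and 2 up, or 3 up adjusted over the list alone (median −0.48, adjusted p = 9.5e-06; adjusted p = 0.088 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 1.88 ± 0.04 and Cdk1, the mitotic kinase, by 1.71 ± 0.04. Of 12 p53 targets, 10 rose and 1 fell (median 0.39, adjusted p = 0.0037; adjusted p = 0.088 with an estimated correlation), with Bax, a pro-apoptotic gene, at 0.55 ± 0.05. Of 6 heat shock genes, 5 rose and 1 fell (median 0.36, adjusted p = 0.018; adjusted p = 0.15 with an estimated correlation), and Hsph1, a chaperone, rose by 0.41 ± 0.06. The YAP list had 8 of 12 genes down, or 9 adjusted over the list alone, and 1 up (median −0.33, adjusted p = 0.010; adjusted p = 0.12 with an estimated correlation), Ccn2 falling by 0.49 ± 0.05. Of 15 acute phase genes 10 fell and 4 rose (median −0.55, adjusted p = 0.0064; adjusted p = 0.28 with an estimated correlation). Fgb, a fibrinogen chain, fell by 1.42 ± 0.04, and Crp, C-reactive protein, was among the 4 that rose, at 1.14 ± 0.07.

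Rhob, a gene fixed beforehand, was not called with SQ1, at 0.05 ± 0.03 (adjusted p = 0.11). It passed with the mean of its probes, at 0.14 (adjusted p = 0.0011), with median centring, at 0.17, and with the Agilent processed signals, at 0.08. Several lists did not pass with SQ1. Actin and SRF targets had 4 of 16 up and 7 down (median −0.08, 0.04 with median centring; adjusted p = 0.22), and Acta2, smooth muscle actin, fell by 0.60 ± 0.06. The stress list had 6 of 16 up and 8 down (median −0.08, 0.06 with median centring; adjusted p = 0.55), Atf3 rising by 0.76 ± 0.07 and Xbp1 falling by 0.57 ± 0.04, both of them stress-response transcription factors. Of 5 AHR targets, 2 rose and 1 fell (adjusted p = 0.55), and Ugt1a6, a glucuronosyltransferase, rose by 0.84 ± 0.05.

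Of 20395 genes tested, 13038 were called with SQ1, 6670 up and 6368 down, and 1527 of them changed at least 1.5-fold (623 up and 904 down). Each gene described above as having risen or fallen did so on 8 of 8 arrays, with an adjusted p of 1.2e-05 or less. Counts adjusted over the list alone equal those over all genes, here and for pravastatin and the difference, except where both are given. Fitted within each culture series, 10281 and 12786 genes were called, and 12874 with the random replicate block. Of the 15 lists called, none kept its call with an estimated correlation, and all 15 passed with fry. A further 6 lists that camera did not call passed with fry as well. Since 63.9% of all genes were called and fry sets a list against no other genes, its passes set the 15 lists little apart.

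**Figure D1:**
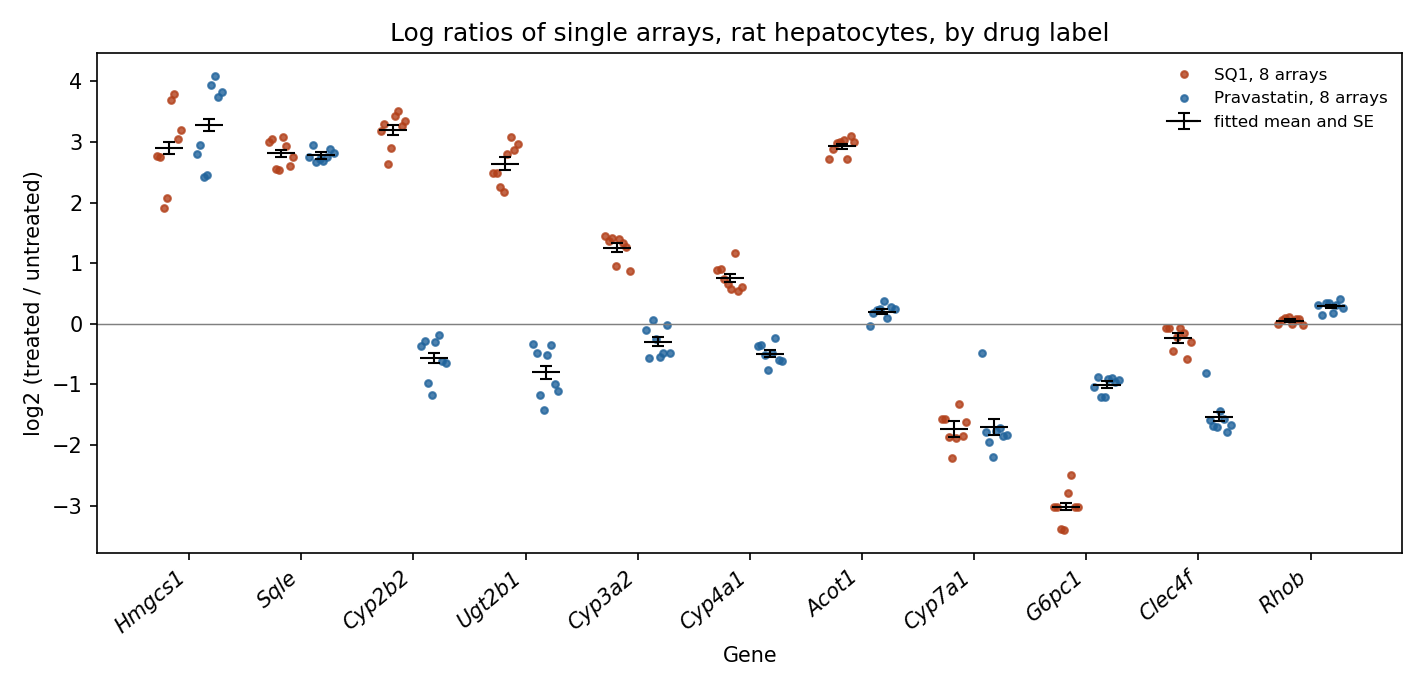
Log2 ratios of treated over untreated cells for 11 genes, with 1 point per array (8 arrays per drug) that is not corrected for the dye effect, and black marks for the fitted mean and its SE, in which the dye effect is removed. Sqle was raised on the arrays of both drugs, and Cyp2b2 was at 3.19 with SQ1, while its pravastatin points lay below 0.

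The second comparison asked which transcripts change with pravastatin. On its arrays, all 20 cholesterol synthesis genes rose, by a median of 2.80 (adjusted p = 9.3e-41), and the call held with an estimated correlation (adjusted p = 0.015). Idi1 rose by 4.44 ± 0.08 or 21.7-fold, Acat2 by 3.89 ± 0.07, Hmgcs1, the HMG-CoA synthase, by 3.28 ± 0.10, Sqle by 2.78 ± 0.06, Fdps, which makes farnesyl diphosphate, by 2.21 ± 0.06 and Fdft1 by 1.98 ± 0.05. Scd2 rose by 5.03 ± 0.13 or 32.8-fold, the largest rise of a gene with a symbol. All 15 macrophage markers fell, by a median of 0.79, and 17 of 20 hepatocyte function genes fell. The cholesterol list's median was 2.79 in the first culture series and 2.72 in the second.

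Lipid genes other than those of cholesterol synthesis rose with pravastatin too. Of 9 genes of sterol-regulated uptake and sensing, 7 rose (median 0.89, adjusted p = 2.0e-09), which held with an estimated correlation (adjusted p = 0.030), with Insig1 at 2.62 ± 0.04. Of 14 genes of fatty acid and triglyceride synthesis, 9 rose and 3 fell (median 0.56, adjusted p = 6.6e-05; adjusted p = 0.088 with an estimated correlation), with Elovl6 at 2.54 ± 0.10 and Acss2, which activates acetate, at 2.50 ± 0.05. LXR targets had 2 of 9 up and 4 down, or 5 adjusted over the list alone, and did not pass (median −0.08, adjusted p = 0.073), though they did within the second culture series (adjusted p = 0.023). Abcg5 rose by 1.24 ± 0.13, Abcg1 fell by 1.17 ± 0.10 and Abca1 stood at −0.05 ± 0.05 (adjusted p = 0.45).

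Drug metabolism and antioxidant genes fell with pravastatin. Of 19 CAR and PXR targets, 16 fell and 1 rose (median −0.41, adjusted p = 9.4e-08; adjusted p = 0.032 with an estimated correlation). Cyp3a18, a drug-metabolising cytochrome P450, fell by 1.94 ± 0.09, Cyp3a23-3a1 by 1.49 ± 0.14, Cyp2c7 by 0.83 ± 0.09 and Cyp3a2 by 0.30 ± 0.07, on 7 of 8 arrays. The Cyp3a2 call was lost within the second culture series (adjusted p = 0.18). Of 14 NRF2 targets, 10 fell and 2 rose (median −0.32, adjusted p = 6.6e-05; adjusted p = 0.032 with an estimated correlation), with Akr7a3, an aldehyde reductase, down by 0.96 ± 0.03, Gsta2, a glutathione transferase, by 0.85 ± 0.04 and Gclc, of glutathione synthesis, by 0.71 ± 0.04. Of 30 PPARalpha targets, 11 fell and 5 rose, or 6 adjusted over the list alone (median −0.05, 0.02 with median centring; adjusted p = 0.25). That list passed within the second culture series alone, where its median was −0.14 (adjusted p = 0.0022). Ehhadh, of peroxisomal oxidation, fell by 0.53 ± 0.06, Cyp4a1 fell by 0.49 ± 0.06 and Angptl4, a lipase inhibitor, rose by 0.44 ± 0.03. Of 5 AHR targets, 2 rose and 3 fell (median −0.19, adjusted p = 0.39), Cyp1a1 rising by 0.95 ± 0.12 and Cyp1a2 falling by 0.77 ± 0.12, both cytochromes P450 of arene metabolism.

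Hepatocyte genes fell with pravastatin, together with macrophage markers. In the hepatocyte function list 17 of 20 genes fell and 2 rose (median −0.41, adjusted p = 4.1e-09; adjusted p = 0.080 with an estimated correlation), with Cyp2e1, a cytochrome P450 of ethanol metabolism, down by 1.66 ± 0.13 and Otc, of the urea cycle, by 0.96 ± 0.06. Bile acid synthesis and transport had 13 of 15 genes down (median −0.44, adjusted p = 9.8e-09; adjusted p = 0.088 with an estimated correlation), with Cyp7a1 down by 1.70 ± 0.13, Nr0b2, a repressor of bile acid synthesis, by 1.54 ± 0.15 and Slc10a1 by 1.48 ± 0.12. Of 13 genes of glucose metabolism, 7 fell (median −0.14, adjusted p = 0.00017; adjusted p = 0.032 with an estimated correlation), among them G6pc1 by 1.00 ± 0.06. The 15 macrophage markers had a median of −0.79 (adjusted p = 4.1e-17; adjusted p = 0.040 with an estimated correlation), −0.74 in the first culture series and −0.86 in the second. Clec4f, a lectin of Kupffer cells, the liver's resident macrophages, fell by 1.53 ± 0.08, Cd68, a lysosomal protein, by 1.04 ± 0.06, Aif1 by 1.03 ± 0.07 and C1qc, a complement subunit, by 0.96 ± 0.03.

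Further lists passed with pravastatin. The cell cycle list had 13 of 21 genes down, or 16 adjusted over the list alone, and 2 up (median −0.21, adjusted p = 8.0e-06; adjusted p = 0.080 with an estimated correlation), Cdk1 falling by 0.46 ± 0.04. Rhob rose by 0.29 ± 0.03. The stress list had 8 of 16 genes down, or 10 adjusted over the list alone, and 1 up (median −0.10, adjusted p = 0.043; adjusted p = 0.34 with an estimated correlation). It lost its call within the second culture series (adjusted p = 0.23) and with the filter at 16 of 32 channels (adjusted p = 0.052), and Trib3, a pseudokinase, fell by 0.30 ± 0.06, on 7 of 8 arrays, but not within the second series (adjusted p = 0.082). Acute phase genes had 10 of 15 down and 3 up, or 5 adjusted over the list alone (median −0.25, adjusted p = 0.017; adjusted p = 0.37 with an estimated correlation), and did not pass within the second series (adjusted p = 0.063). C3, complement component 3, fell by 0.54 ± 0.05 and A2m, a protease inhibitor, rose by 0.85 ± 0.11.

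The other lists did not pass with pravastatin. Actin and SRF targets had 2 of 16 up and 7 down (median −0.07, adjusted p = 0.23), and YAP targets 2 of 12 up and 3 down (median −0.03, adjusted p = 0.60), Ccn2 rising by 0.31 ± 0.05 on 7 of 8 arrays. None of 6 heat shock genes was called by limma, with 2 at an unadjusted p under 0.05 (median 0.04, adjusted p = 0.63). Of 12 p53 targets, 3 rose and 2 fell (adjusted p = 0.60), with a median of −0.00 that was 0.02 with median centring and a mean of 0.03. Bax rose by 0.16 ± 0.05, on 6 of 8 arrays, but not within the first series (adjusted p = 0.25). Stellate cell and fibroblast markers had 5 of 11 down and 1 up (median −0.12, −0.04 and −0.17 in the culture series; adjusted p = 0.097), with Lrat down by 0.38 ± 0.06. Endothelial markers had 3 of 7 down (median −0.09, −0.16 with the Agilent processed signals and −0.06 within the first culture series; adjusted p = 0.25), with Clec14a down by 0.24 ± 0.05. Cholangiocyte markers had 3 of 7 up and 1 down (median 0.01, −0.03 with median centring; adjusted p = 0.35), with Epcam up by 0.37 ± 0.03.

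With pravastatin 7965 genes were called, 3953 up and 4012 down, and 400 of them changed at least 1.5-fold (200 up and 200 down). Except where the number of arrays is given, each gene described as having risen or fallen did so on 8 of 8 arrays, and no adjusted p of a called gene above exceeded 0.0090. Within the culture series 3979 and 8730 genes were called, and 7895 with the random replicate block. Of the 12 lists described here as called, 6 kept their call with an estimated correlation. When arrays were scaled to 1 spread, several medians with pravastatin were larger in size, at 4.15 for cholesterol synthesis, 1.34 for sterol-regulated uptake and sensing, −0.66 for hepatocyte function and −0.42 for acute phase genes. They were −0.26 for glucose metabolism, −0.19 for the stress list, −0.31 for AHR targets and −0.15 for LXR targets. The glucose metabolism median was −0.25 within the second culture series.

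**Figure D2:**
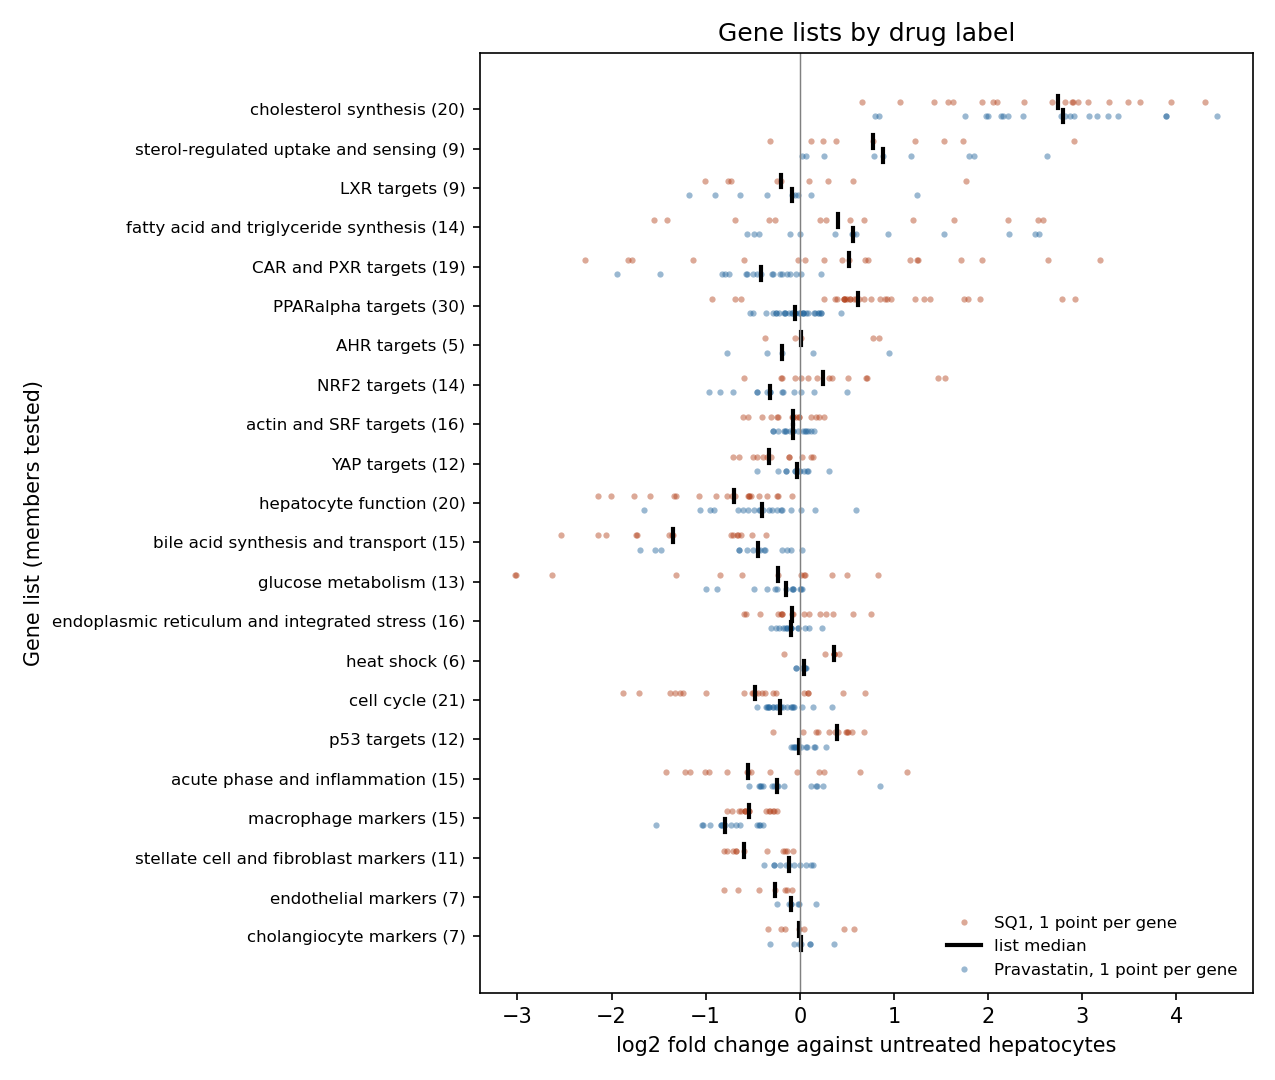
Log2 fold changes of the members of 22 gene lists, with SQ1 (upper points of each list) and pravastatin (lower points) against untreated cells, 1 point per gene, and a black mark for the list median. The cholesterol synthesis medians were 2.75 and 2.80, and the PPARalpha medians 0.61 and −0.05, the latter 0.02 with median centring.

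The third comparison set SQ1 against pravastatin directly, and asked where block of the pathway at squalene synthase and block upstream of it differ. PPARalpha, NRF2, and CAR and PXR targets were higher with SQ1 than with pravastatin, and genes of bile acids and the cell cycle were lower. Of these lists, only those of PPARalpha and NRF2 kept their call with an estimated correlation. Cyp2b2 differed by 3.76 ± 0.12 or 13.6-fold, Ugt2b1 by 3.44 ± 0.15, Cyp3a23-3a1 by 3.43 ± 0.20, Acot1 by 2.73 ± 0.06 and Cyp4a2 by 2.59 ± 0.15, all higher with SQ1. Pklr, Slc27a5 and G6pc1 were lower with SQ1, at −2.55 ± 0.16, −2.16 ± 0.09 and −2.02 ± 0.08. When arrays were scaled to 1 spread, G6pc1 was at −0.81 and lost its call (adjusted p = 0.18). The doses of the drugs differed, so these values do not compare them at a matched dose. The drugs were also on separate slides, so an effect of slide on the ratios is not separated from these differences.

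Of 30 PPARalpha targets, 25 were higher with SQ1 and 3 lower (median 0.71, adjusted p = 1.6e-18; adjusted p = 0.010 with an estimated correlation), with Pdk4 at 1.69 ± 0.13 and Cyp4a1 at 1.25 ± 0.09. Of 14 NRF2 targets, 13 were higher and 1 lower (median 0.53, adjusted p = 1.5e-09; adjusted p = 0.0068 with an estimated correlation), with Hmox1 at 1.79 ± 0.09 and Gsta2 at 1.36 ± 0.06. Of 19 CAR and PXR targets, 12 were higher and 3 lower (median 0.73, adjusted p = 1.1e-06; adjusted p = 0.052 with an estimated correlation), with Cyp3a2 at 1.55 ± 0.10. Of 12 p53 targets 9 were higher and 1 lower (median 0.32, 0.21 when arrays were scaled to 1 spread; adjusted p = 0.00088; adjusted p = 0.063 with an estimated correlation). Of 6 heat shock genes 5 were higher (median 0.31, 0.20 with that scaling; adjusted p = 0.0041; adjusted p = 0.096 with an estimated correlation), and 1 was lower adjusted over the list alone.

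Cell type markers differed as well. Of 15 macrophage markers, 8 were higher with SQ1, or 9 adjusted over the list alone, and 1 lower (median 0.22, 0.70 when arrays were scaled to 1 spread; adjusted p = 0.00082; adjusted p = 0.41 with an estimated correlation), with Clec4f at 1.29 ± 0.11 and Cd68 at 0.71 ± 0.09. Gpnmb, a glycoprotein of macrophages and other cells that is in no list, was higher by 2.38 ± 0.09. Of 11 stellate cell and fibroblast markers, 8 were lower with SQ1, or 9 adjusted over the list alone (median −0.40, −0.21 when arrays were scaled to 1 spread; adjusted p = 0.00022; adjusted p = 0.038 with an estimated correlation), with Col1a1, a fibrillar collagen, at −0.73 ± 0.10. Of 7 endothelial markers 4 were lower (median −0.24, −0.39 with the Agilent processed signals and −0.15 within the second culture series; adjusted p = 0.0097; adjusted p = 0.062 with an estimated correlation), with Lyve1 at −0.98 ± 0.11. Of 7 cholangiocyte markers, 2 were higher and 1 lower (median −0.02, −0.15 within the second culture series, mean 0.02, adjusted p = 0.92).

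Hepatocyte function had 14 of 20 genes lower with SQ1 (median −0.39, but 0.05 when arrays were scaled to 1 spread; adjusted p = 8.7e-07; adjusted p = 0.11 with an estimated correlation), and 1 higher adjusted over the list alone. Cps1 was at −1.04 ± 0.10, and at −0.44 with that scaling, where its call was lost (adjusted p = 0.14). Of 15 genes of bile acid synthesis and transport, 11 were lower, or 12 adjusted over the list alone, and 1 higher (median −0.49, −0.23 with that scaling; adjusted p = 1.1e-06; adjusted p = 0.14 with an estimated correlation), with Cyp8b1 at −1.56 ± 0.12 and Cyp7a1 at −0.04 ± 0.19 (95% confidence interval −0.43 to 0.35). With that scaling Cyp7a1 turned to 0.71 and gained a call (adjusted p = 1.8e-05). Of 21 cell cycle genes 16 were lower and 3 higher, or 4 adjusted over the list alone (median −0.27, adjusted p = 2.1e-05; adjusted p = 0.096 with an estimated correlation), with Rrm2 at −1.52 ± 0.06 and Cdk1 at −1.25 ± 0.05. Of 12 YAP targets 6 were lower, or 8 adjusted over the list alone (median −0.23, −0.14 with that scaling; adjusted p = 0.0061; adjusted p = 0.10 with an estimated correlation), with Ccn2 at −0.80 ± 0.07. Of 15 acute phase genes 10 were lower and 2 higher (median −0.29, −0.01 with that scaling and −0.63 within the second culture series; adjusted p = 0.0022; adjusted p = 0.29 with an estimated correlation), and the list did not pass within the first culture series (adjusted p = 0.071).

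The cholesterol synthesis list did not pass for the difference, with 2 of 20 genes higher and 7 lower with SQ1 (median −0.11, adjusted p = 0.31). Its median depended on the scale of the arrays, at −1.95 when they were scaled to 1 spread. Within the second culture series that list passed, at a median of −0.17 (adjusted p = 0.00018), whereas its median was 0.03 in the first. Sqle differed by 0.03 ± 0.08 (95% confidence interval −0.14 to 0.21). It was higher with SQ1 in the first culture series, by 0.23 (adjusted p = 0.023), and lower in the second, at −0.16 (adjusted p = 0.019). Dhcr7, the last enzyme of cholesterol synthesis, was lower at −0.57 ± 0.08 and Fdft1 at −0.35 ± 0.07, whereas Insig1 was higher by 0.29 ± 0.06, a direction that turned to −1.65, with no call, when arrays were scaled to 1 spread (adjusted p = 0.28). That scaling put Dhcr7 at −1.91 (adjusted p = 0.11), Fdft1 at −1.76 (adjusted p = 0.17) and Hmgcs1 at −2.50 (adjusted p = 0.13), so that larger values lost their calls. Hmgcs1 stood at −0.37 ± 0.14 (adjusted p = 0.043), a call lost with the slide as a block (adjusted p = 0.065), with median centring (adjusted p = 0.055), with no filter (adjusted p = 0.052) and with no dye term (adjusted p = 0.40). It was also lost without SQ1 replicate 3, 4, 7 or 8 or pravastatin replicate 1, 2, 5, 6 or 8, at an adjusted p of 0.059 to 0.094.

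Other lists did not pass for the difference. Sterol-regulated uptake and sensing had 2 of 9 genes higher with SQ1 and 3 lower, or 5 adjusted over the list alone (median −0.11, −0.73 when arrays were scaled to 1 spread; adjusted p = 0.35), and passed within the second culture series (adjusted p = 0.042). LXR targets had 4 of 9 higher and 2 lower (median 0.17, 0.34 with the Agilent processed signals; adjusted p = 0.17), and passed within the second series, at a median of 0.25 (adjusted p = 0.043). Abca1 differed by 0.15 ± 0.07 (adjusted p = 0.099), and passed with the random (adjusted p = 0.021) and fixed (adjusted p = 0.0085) replicate block and without pravastatin replicate 2 (adjusted p = 0.046). Fatty acid and triglyceride synthesis had 4 of 14 higher, or 5 adjusted over the list alone, and 6 lower (adjusted p = 0.75), with a median of 0.04, a mean of −0.19 and a median of −0.27 when arrays were scaled to 1 spread. Its median was 0.11 in the first culture series and −0.19 in the second. In it Acly, which makes cytosolic acetyl-CoA, was lower at −1.24 ± 0.13 and Fasn, fatty acid synthase, at −0.73 ± 0.15. Glucose metabolism had 4 of 13 higher and 6 lower (median 0.04, mean −0.49, adjusted p = 0.35). AHR targets had 3 of 5 higher and 2 lower (median 0.20, 0.32 when arrays were scaled to 1 spread, 0.31 and 0.09 in the culture series; adjusted p = 0.35), with Cyp1a2 at 1.55 ± 0.16 and Cyp1a1 at −1.01 ± 0.18. Actin and SRF targets had 1 of 16 higher and 3 lower (median −0.05, 0.01 with median centring; adjusted p = 0.58), and the stress list 7 of 16 higher and 4 lower, or 5 adjusted over the list alone (median 0.00, adjusted p = 0.64). Rhob was lower with SQ1, at −0.24 ± 0.04.

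Between the drugs 7760 genes differed, 3779 higher and 3981 lower with SQ1, and 859 of them by at least 1.5-fold (396 higher and 463 lower). Each gene given as higher or lower was so in 8 of 8 same-numbered pairs of arrays. Of the 13 lists called, 3 kept their call with an estimated correlation. Within the culture series 4801 and 7670 genes differed, 9750 with the random and 9737 with the fixed replicate block, and 3818 when arrays were scaled to 1 spread.

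The last comparison asked how far the drugs share a response. Of the genes called, 3082 rose with both and 3089 fell with both, where independent lists would give 1293 and 1253 and simulations of unchanged genes gave 0. Genes simulated as unchanged are almost never called, so that 0 cannot show how far shared controls enlarge the overlap. The values for independent lists leave shared controls out too. At a change of at least 1.5-fold, 154 rose with both and 135 fell with both, against 6.1 and 8.9 for independent lists. A further 371 genes rose with SQ1 and fell with pravastatin, and 253 did the opposite, against 1312 and 1234 for independent lists. At 1.5-fold or more in both, 10 genes rose with SQ1 and fell with pravastatin, against 6.1 for independent lists, and 0 did the opposite, against 8.9. Of the 10, 6 have a symbol: Cyp1a2, Cyp2c6v1, Cyp3a23-3a1, Gsta5, Sult1c2a and Ugt2b1, picked out after their values had been seen. Across all genes the log2 fold changes correlated at 0.694, and 73.2% had the same sign.

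Scanner file names give same-numbered arrays of both drugs the same control number. If those arrays share untreated RNA, unchanged genes would already correlate, at 0.502 in simulation. The simulation assumed equal shares of the spread for treated and untreated RNA, which sets that value by construction and was not estimated from these arrays. Under the same assumption the covariance of unchanged genes would be 0.000857, against 0.0582 observed. With SQ1 arrays of odd number set against pravastatin arrays of even number, and the reverse, no control number was shared. The correlation was then 0.677 and 0.678. With as many arrays but the same numbers for both drugs, it was 0.690 for odd and 0.686 for even numbers. Fitted within each culture series, the log2 fold changes of the 2 series correlated across genes at 0.931 for SQ1 and at 0.893 for pravastatin.

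**Figure D3:**
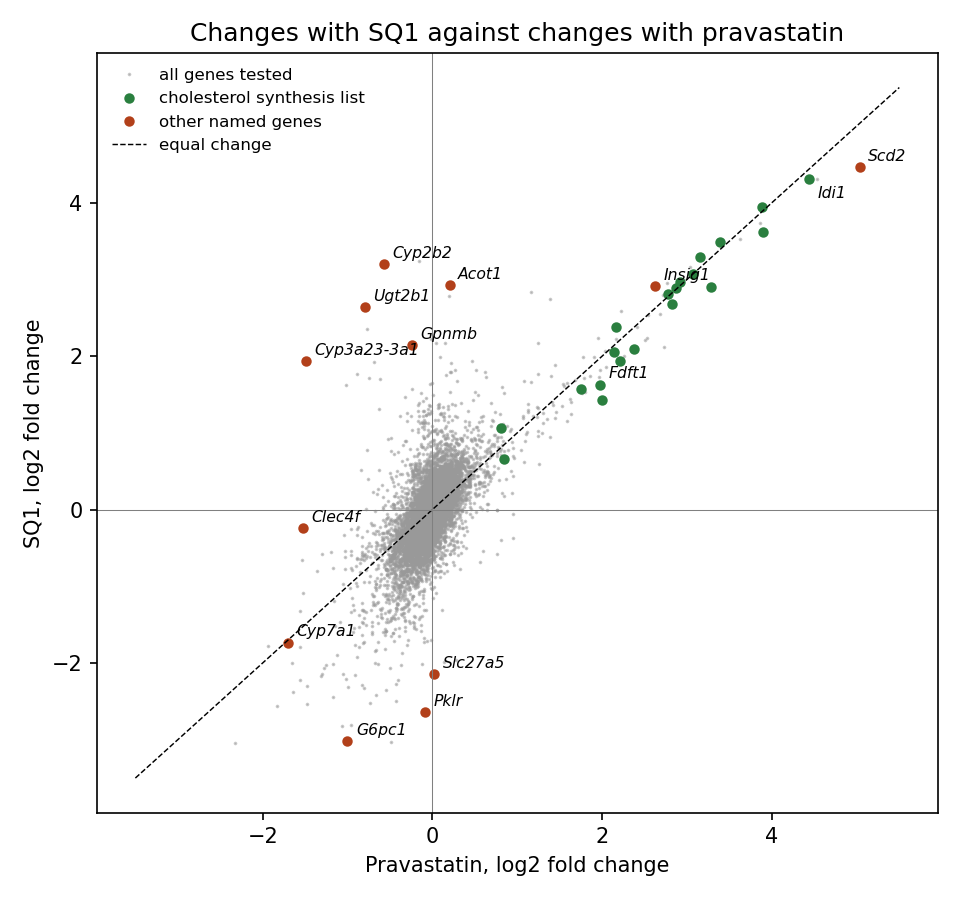
Log2 fold change with SQ1 (vertical axis) against that with pravastatin (horizontal axis) for 20395 genes, with cholesterol synthesis genes in green, other named genes in red and a dashed line of equal change. Cholesterol synthesis genes lie near the line in the fit shown, Cyp2b2, Ugt2b1 and Acot1 lie far above it, and Pklr and Slc27a5 lie far below it.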

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

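The tests of macrophage and hepatocyte markers below were chosen after the results had been seen; the tests of the exchanged columns and of other splits of the arrays were set before.

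The columns of the deposited value table held the same-numbered array of the other drug, with a correlation across probes of at least 0.938. Either the table or the scanner files may carry the wrong drug names. If the scanner files did, Cyp2b2, a CAR target that squalene synthase inhibition is known to raise, would be lower on the SQ1 arrays, but it was higher by 3.76 ± 0.12. Rhob, which statins are known to raise, would be higher on the SQ1 arrays, but was lower, at −0.237 ± 0.0398. Both values argue against wrong names on the scanner files, as far as the known drug effects hold, and leave an exchange of columns in the table open, which was not tested further. No biological explanation was tested.

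Macrophage markers fell on the pravastatin arrays, which an altered share of RNA from all non-hepatocyte cells might explain. That would move the markers of every such cell type alike. The median of the 15 macrophage markers minus that of the other 25 non-hepatocyte markers was taken on each array. It averaged −0.729 ± 0.0365 and was below 0 on 8 of 8 arrays. This argues against that explanation only as far as the 25 markers report other cells. These arrays cannot tell how many of them hepatocytes also express. The fall was not a matter of 1 culture series, since the macrophage medians of single arrays averaged −0.701 ± 0.0387 in the first and −0.870 ± 0.0134 in the second. The brightest of the markers, C1qb and Lyz2, fell by 0.84 ± 0.03 and 0.68 ± 0.07. A drug effect on macrophages, through fewer cells or lower transcription, is a candidate explanation that stays open and was not tested.

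Hepatocyte function genes fell on the SQ1 arrays, for which a lower share of hepatocyte RNA is a candidate explanation. It would raise the markers of every other cell type, but the median of the 40 non-hepatocyte markers, taken on each array, averaged −0.395 ± 0.0314 and below 0 on 8 of 8 arrays. Among these, the 7 cholangiocyte markers did not move 1 way, with 2 up and 3 down, a median of −0.01 and a mean of 0.05. The fall of the hepatocyte function genes was present in both culture series, where the medians of their list on single arrays averaged −0.613 ± 0.037 and −0.810 ± 0.0394. The labels name no sort of the cells, and these arrays cannot tell how many of the marker genes hepatocytes also express. An effect of SQ1 on these genes stays open as a hypothesis.

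Of the 99 combinations of gene and drug examined, 4 had 1 array far from the other 7, all of them pravastatin replicate 1, where chance alone would set apart about 1 in 20. The gap to the nearest array, as a share of the whole range, was 0.646 for Ropn1l (3.83 on that array, 4.45 to 4.79 on the others). It was 0.702 for Cyp7a1 (−0.49 against −2.22 to −1.70), 0.594 for Nr0b2 (−0.20 against −2.19 to −1.38) and 0.568 for Clec4f (−0.87 against −1.76 to −1.38), each above Dixon's 95% critical value for 8 arrays. Without that array 13025 genes were called for SQ1, 8052 for pravastatin and 7493 for the difference.

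In 624 genes SQ1 and pravastatin had called changes of opposite sign, with a called difference. The SQ1 effect differed between the culture series in 3048 genes and the pravastatin effect in 1023. Genes called in both series had opposite signs in 73 cases and the same sign in 8894 with SQ1, and in 24 and 3418 with pravastatin.

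The 3 counts of called genes were set against other splits of the arrays, and no other split drawn called as many. Of 100 sign assignments of the SQ1 arrays, drawn from 128, 1 called as many as the real 13038 genes, the real one itself, and the highest other called 10795. For pravastatin it was 1 of 100, with 7965 and 5281, and for exchanges of drug names within the same-numbered pairs 1 of 100, with 7760 and 4087. Each highest other split differed from the real one by replicate 6 alone. Arrays of a drug correlated with each other, so turning any of them was likely to lower the count whatever its size. The splits therefore show that the arrays of a drug share a direction, and cannot tell how many of the called genes are due to chance.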

How the results depend on the processing

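Scaling between arrays and the matched value table were tests added after the data had been seen; the other alternatives were set before. Of the 4690 values that alternatives gave for named genes, 4591 kept their side of the threshold and, where called, their direction. A value called neither before nor after counts as kept even if its sign turned. By the same rule 467 of 528 values for gene lists were kept. Of 119 counts and correlations, 111 stayed within 1.5 times the reported count or within the spread of the correlation. Leaving out 1 array gave 12357 to 13075 genes for SQ1, 6926 to 8103 for pravastatin and 7077 to 7867 for the difference. With a change of at least 1.5-fold, which by construction keeps fewer genes, the counts were 1527, 400 and 859. The first culture series alone called 3979 genes for pravastatin and 4801 for the difference, where the second, with as many arrays, called 8730 and 7670. Scaling the arrays to 1 spread gave 3818 genes for the difference and turned the differences of Cyp7a1 (0.71, which gained a call) and Insig1 (−1.65, which lost it). It also ended the calls of Fdft1 with SQ1 (1.27) and, for the difference, of G6pc1 (−0.81), Cps1 (−0.44), Dhcr7 (−1.91), Fdft1 (−1.76) and Hmgcs1 (−2.50), and moved the median of the cholesterol list's difference from −0.11 to −1.95. The correlation of the drugs was 0.664 with the Agilent processed signals. The Sqle difference was −0.16 in the second culture series. For the changes with a culture series and with the processed signals the cause was not tested. Scaling gives all arrays 1 spread by construction, though log2 fold changes varied more with SQ1 (variance 0.134) than with pravastatin (0.0523). It thus shrank the cholesterol list's median with SQ1 from 2.75 to 2.13 and enlarged that with pravastatin from 2.80 to 4.15. The shift of that list's difference follows from this, and the cause of single lost or gained calls was not tested. Quantile normalisation of mean signals left the log ratios as they were, by construction. Its values are in the totals above, as are those of the matched value table, which nearly repeat the Agilent processed signals. With fry and the estimated correlation a list could gain or lose a call but not turn. The totals therefore overstate how much was put to a test. Each of the 77 genes given in the comparisons had at least 1 probe above background in each channel of every array, though not necessarily the probe whose value is given.

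Read as labelled, the value table called 13428 genes for pravastatin, since its columns hold the arrays that the scanner files assign to the other drug. It turned the sign of 53 gene values, counting only those called in at least 1 of the 2 readings. With SQ1 these log2 fold changes were Cyp2b2 −0.59, Ugt2b1 −0.82, Cyp3a23-3a1 −1.53, Cyp3a2 −0.39, Cyp4a1 −0.50, Hmox1 −0.37, Slc27a5 0.00332, Lyve1 0.14, Ugt1a6 −0.34, Ccn2 0.32 and Atf3 −0.035. With pravastatin they were Abca1 0.14, Cyp3a23-3a1 1.98, Cyp3a2 1.43, Cyp4a1 0.77, Ehhadh 0.95, Gsta2 0.54, Cyp1a1 −0.037, Cyp1a2 0.85, Ccn2 −0.51 and Trib3 0.24. For the difference they were Cyp2b2 −3.80, Ugt2b1 −3.48, Cyp3a23-3a1 −3.51, Cyp3a2 −1.82, Cyp4a1 −1.28, Acot1 −2.78, Cyp4a2 −2.65, Pdk4 −2.01, Hmox1 −1.90, Gsta2 −1.38, Cyp1a2 −1.75, Cyp1a1 1.05, Pklr 2.57, G6pc1 2.04, Slc27a5 2.14, Cyp8b1 1.80, Acly 1.26, Fasn 0.70, Hmgcs1 0.41, Fdft1 0.32, Dhcr7 0.56, Insig1 −0.31, Rhob 0.21, Clec4f −1.52, Cd68 −0.75, Rrm2 1.60, Cdk1 1.36, Col1a1 0.93, Lyve1 1.01, Gpnmb −2.42, Ccn2 0.82 and Cps1 1.03.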

Other observations

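The tests of gene families, by the letters a symbol starts with, were chosen after the data had been seen. With 10 or more tested members, 140 families were tested with camera in each comparison, of which 16 were called for SQ1, 11 for pravastatin and 6 for the difference. With an estimated correlation 1, 0 and 2 of them kept their call.

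Acyl-CoA thioesterases, which free fatty acids from coenzyme A, rose with SQ1 in 8 of 10 cases and fell in 2 (Acot family, median 1.02, adjusted p = 0.0032; adjusted p = 0.15 with an estimated correlation). Acot2 stood at 1.75 ± 0.05, Acot5 at 1.59 ± 0.05 and Acot4 at 1.22 ± 0.04, and Acot12 fell by 0.43 ± 0.05. Their difference between the drugs was called in 9 of 10 genes, all higher with SQ1 (median 0.76, adjusted p = 3.4e-08; adjusted p = 0.0039 with an estimated correlation). Acot1 and Acot2 are also in the PPARalpha list. Organic anion transporters of the Slco family fell in 9 of 10 cases with SQ1 (median −0.77, adjusted p = 0.0019; adjusted p = 0.49 with an estimated correlation), with Slco1a4 down by 1.82 ± 0.09, Slco1a1 by 1.36 ± 0.06 and Slco2b1 by 1.35 ± 0.04. In the same family 6 of 10 genes fell with pravastatin (median −0.31, adjusted p = 0.020; adjusted p = 0.65 with an estimated correlation).

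Collagen genes fell with SQ1 in 10 of 14 cases (median −0.49, adjusted p = 0.0097; adjusted p = 0.49 with an estimated correlation). Col5a3 fell by 1.99 ± 0.06 with SQ1 and stood at 0.14 ± 0.06 with pravastatin, a difference of −2.13. Of 12 carboxylesterases (Ces family), 7 were higher with SQ1 than with pravastatin (median 0.29, adjusted p = 0.0021; adjusted p = 0.47 with an estimated correlation), with Ces1f at 0.79. With pravastatin 8 of 12 fell and 2 rose (median −0.24, adjusted p = 0.0022; adjusted p = 0.49 with an estimated correlation). Of 60 Cyp genes, 41 fell and 10 rose with pravastatin (median −0.30, adjusted p = 7.8e-06; adjusted p = 0.55 with an estimated correlation). Zinc finger genes of the Zfp family fell slightly with SQ1, 85 of 154 down and 22 up (median −0.11, adjusted p = 0.0018; adjusted p = 0.015 with an estimated correlation).

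Among 1996 tested genes with several probes, 81 had probes called in both directions with SQ1, 15 with pravastatin and 20 for the difference.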
